A study of Mus musculus with 39 samples.

How the data were processed

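Per the labels' protocols, mouse liver and spleen were frozen, RNA was extracted with Trizol, and separate sets of liver and spleen libraries were made with an Illumina TruSeq kit and run on a HiSeq4000, each set in its own lane. The labels name 2 versions of that kit, 1 of them stranded, so the strand setting of the counting is not given in the sources used here. The submitters' processing notes name FastQC, STAR 2.6.0, featureCounts, a DESeq2 version given as 3.8 and the genome build mm10. Their order, options and annotation are not given in the sources used here.

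For each tissue the authors deposited a signal table of normalised read counts with 54735 genes. Each value is a gene's reads divided by 1 size factor per library. Every library's values were whole multiples of a single step, so reads were recovered by division, and 100% of the values above 0 came out whole within 0.05 reads in every library. The authors also deposited tables of their own DESeq2 comparisons with log2 fold changes and p-values. Of these, 1 liver and 1 spleen table list only genes with an adjusted p under 0.05. In each tissue, 26 gene symbols of the signal table had been turned into dates and were restored from the same position in the authors' full comparison table, whose mean values matched. All per-sample columns were matched to a sample by name.

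Groups were taken from the sample titles. Genes with a mean normalised value of at least 10 over a tissue's libraries were tested on log2(value + 1) with limma 3.58.1 (lmFit, contrasts.fit and eBayes with trend) in R 4.3.3, in 1 fit per tissue over its 4 groups. Fold changes are on that scale, which understates the change of low genes. The contrasts were PCB-153 against vehicle within each genotype, knockout against wild type within each exposure, and the interaction. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method, and genes with an adjusted p under 0.05 are called higher or lower, rose or fell. Before the data were examined, 43 gene lists were fixed for drug metabolism, liver functions and the cell types that either tissue could hold. Each was tested with camera at a preset correlation of 0.01 where at least 5 members were measured, adjusted over the lists of a tissue, and again with the correlation estimated. In spleen the pancreatic and hepatocyte lists served as markers of neighbouring organs.

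The genes named were chosen by a rule fixed before the data were examined. Named are Nr1i2, and in each comparison the 8 genes with the largest rise and the 8 with the largest fall among called genes with a mean of at least 50, or all called genes where there were fewer than 16, leaving out predicted genes. Added to these are up to 4 called members with the smallest p of each list that passed camera or had 3 called members, Cyp3a11, Cyp2b10, Cyp2c55, Cyp1a1 and Cyp1a2 in liver, Alas2, Cd79a and Cd3e in spleen, up to 10 called genes for the interaction, and 5 sex-linked genes per library. A gene named outside this rule in the part on chromosome 16 or in the closing part was chosen after its values were seen.

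Alternatives fixed before the data were examined were pseudocounts of 0.5 and 5, no filter on low values or a minimum mean of 50, quantile normalisation, a fit of the 2 compared groups only, the replicate number as a block, each library left out in turn, and edgeR 4.0.16 (quasi-likelihood test, TMM) and DESeq2 1.42.0 (Wald test) on the recovered reads. A sex-marker covariate had been planned for the case of both sexes and was not run because every library carried the male pattern. Others, named where they are used, were chosen after the data were examined. Libraries held 15.23 to 29.52 M reads, and the median standard error per gene was 0.17 in liver and 0.123 to 0.13 in spleen for comparisons of 2 groups on the log2 scale. Replicates differed by more than counting error, with a chi-square per degree of freedom of at least 9.98 in liver and 4.67 in spleen.

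The limma fit was tested on reads simulated from each gene's mean and estimated spread, with known changes in the comparison of exposures in knockout. In liver it recovered 81.8% of genes changed by a log2 size of 1 and 95.9% at a size of 2, with 5 of 15879 unchanged genes called. In spleen it recovered 83.8% and 100%, with 3 of 18773 called. Camera with the preset correlation was tested on 1000 random lists of 25 genes in the same simulated reads and gave an unadjusted p under 0.05 for 1.1% of them. The reads of each gene were drawn independently of other genes. These rates therefore need not hold for genes that vary together between libraries.

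Gene positions are from the GENCODE M21 annotation of GRCm38, matched by symbol. Sequence shared between genes was measured as the share of a gene's 50-base words, over its annotated transcripts, that occur in another gene. A count over a whole gene does not separate exons or transcripts.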

Results

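Messenger RNA was measured by RNA sequencing in liver and spleen of C57BL/6 mice at 4 weeks of age. The mice were wild type or carried a knockout of SXR/PXR, the steroid and xenobiotic receptor, a nuclear receptor that switches on genes for drug metabolism and is encoded by Nr1i2. Per the labels they had received PCB-153, a persistent polychlorinated biphenyl, at about 54 µg per kg per day from the perinatal period on, or the solvent DMSO as vehicle. Crossing genotype and exposure gave 4 groups in each tissue, with 5 libraries in each group except 4 in the wild-type vehicle spleens, 39 libraries in all. Liver libraries held 15.23 to 28.65 M assigned reads (median 19.02 M) and spleen libraries 16.1 to 29.52 M (median 19.64 M). At this depth 16155 genes were tested in liver and 19058 in spleen. The labels name no litters and do not state that the libraries of a group came from separate animals. Pups of 1 litter share their exposure, so p-values measure only the spread between these samples. No 2 libraries of a group were as alike as repeat counts of 1 library would be, the lowest chi-square per degree of freedom being 9.98 in liver and 4.67 in spleen.

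The targeted gene Nr1i2 (chromosome 16, 38248323 to 38294824, GRCm38) was lower in knockout livers but was still counted there. Its normalised read count was 1572 ± 178 (SD, n = 5) in wild-type vehicle livers and 714 ± 192 (n = 5) in knockout vehicle livers, a log2 fold change of -1.18 ± 0.20 (SE, limma adjusted p = 0.00415). After PCB-153 the counts were 1395 ± 390 in wild type and 862 ± 215 in knockout, and this difference did not pass the limma test (log2 fold change -0.69, adjusted p = 0.111). The authors' deposited DESeq2 comparison gives -0.70 with an adjusted p of 0.0402, so the call depends on the test. In spleen the order was the opposite. Nr1i2 was nearly absent from wild-type spleens, at 0.57 ± 1.13 (n = 4) under vehicle and 0.45 ± 1.00 (n = 5) after PCB-153, and stood at 55.5 ± 7.90 and 52.1 ± 5.58 (n = 5 each) in the spleens labelled knockout. These levels rest on 3 and 2 reads in wild type against 288 and 249 reads, a ratio of 76 (exact 95% interval 25.7 to 370, counting error only) under vehicle and 141 (38.6 to 1170) after PCB-153. Which exons were deleted is not given in the sources used here, and a count over the whole gene does not tell reads of retained exons from reads of an intact transcript. Spleen libraries of that genotype are therefore called labelled knockout throughout, and directions between genotypes in spleen rest on that label. Whether the genotype labels of the spleens were exchanged was not tested. Xist, which female cells express from the inactive X chromosome, did not exceed 5.54 in any liver or 14.4 in any spleen, while Y-linked Eif2s3y was at least 582 in liver and 960 in spleen, so every library carried the male pattern.

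**Figure D1:**
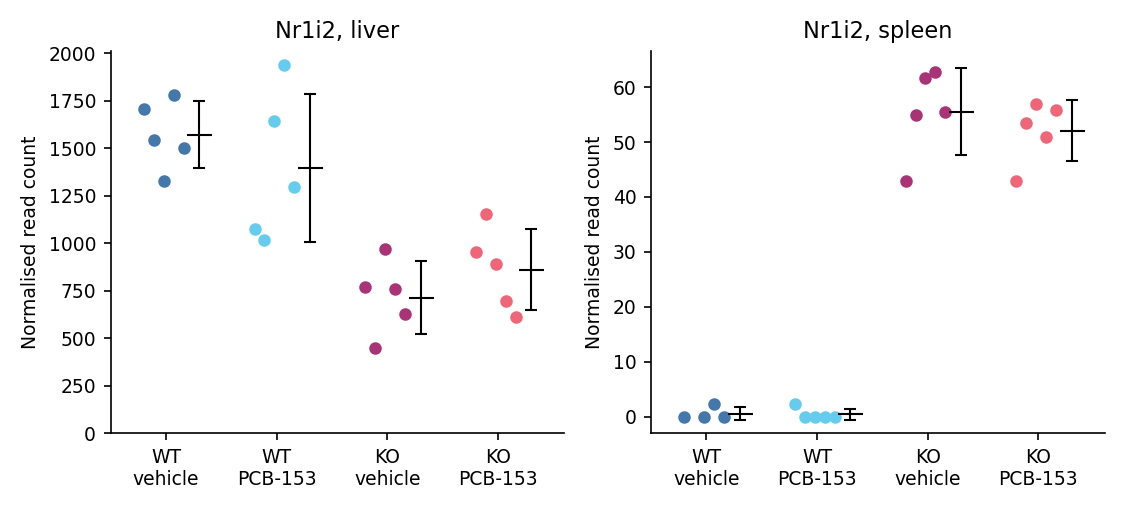
Normalised read count of Nr1i2 in each library of liver (left) and spleen (right), by group, with points for libraries and black bars for group mean ± SD. Liver means range from 714 to 1572, while spleen means are 55.5 and 52.1 in the groups labelled knockout and 0.57 and 0.45 in wild type.

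The comparison of genotypes under vehicle asks what differed between knockout and wild type without PCB-153. It does not separate loss of the receptor from other differences between these mice, such as litter. In vehicle livers the knockout had higher levels of Akr1b7 and of several hydroxysteroid sulfotransferases and lower levels of genes that adult male livers express most. Akr1b7, an aldo-keto reductase (chromosome 6, 34412334 to 34423142), rose from 21.9 ± 6.70 in wild type to 493 ± 290 in knockout (log2 fold change 4.24 ± 0.38, adjusted p = 3.94e-06, n = 5 each). The hydroxysteroid sulfotransferase Sult2a1 rose from 305 ± 272 to 5914 ± 4044 (4.50 ± 0.73, adjusted p = 0.00229), with Sult2a2, Sult2a4 and Sult2a5 higher by 3.53, 3.97 and 4.07. Papss2, which makes the sulfate donor these enzymes use, rose from 3092 ± 627 to 7224 ± 772 (1.25 ± 0.15, adjusted p = 0.000163). Hsd3b5, a steroid dehydrogenase of male liver, fell from 1419 ± 601 to 212 ± 281 (-4.54 ± 0.96, adjusted p = 0.0274). The stem cell surface protein gene Prom1 (2.33), the lipid droplet enzyme gene Pnpla3 (2.11), the aldehyde dehydrogenase gene Aldh1b1 (1.09) and the pseudogene Zbed4-ps1 (4.37) were higher.

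By fixed gene list, all 23 members of the male-biased list had a lower mean in knockout vehicle livers. Of these 10 fell, or 19 adjusted over the list alone, among them Cyp4a12a (-4.21), Cyp2d9 (-2.28), Cspg5 (-2.09), Selenbp2 (-1.33) and Susd4 (-1.58). Also lower were Cyp4a12b (-3.81), Cyp2d12 (-2.22) and the pseudogene Cyp2d41-ps (-2.20), relatives of the hydroxylases above. In the female-biased list 6 of 24 members rose and none fell, or 13 adjusted over the list alone, with Sult2a1, A1bg (3.64) and the transporter Slc22a26 (1.28) among them. Both lists passed camera with the preset correlation (adjusted p = 3.23e-23 and 8.84e-12), but neither call held with a correlation estimated from the data (adjusted p = 0.141 with an estimated correlation for each). The list of phase I xenobiotic enzymes was mixed, with Cyp2c55 higher (1.03) and Cyp3a59 (-1.16) and Cyp2d9 lower among 30 measured, and did not pass (adjusted p = 0.218). The classic SXR target Cyp3a11 was at 80030 ± 22630 in knockout and 102000 ± 13180 in wild type, within the spread between replicates (-0.39 ± 0.17, adjusted p = 0.356), and Cyp1a2, which oxidises aromatic amines, differed by -0.70 (adjusted p = 0.188). The conjugation list had Papss2 higher and the glutathione transferase Gstp1 (-1.10) lower among 31, and passed with the preset correlation only (adjusted p = 0.021, and adjusted p = 0.493 with an estimated correlation).

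In total, limma called 98 genes between vehicle livers, 54 higher and 44 lower in knockout, 59 of them by more than 2-fold. Of the named genes, Sult2a2 has 62.1% of its 50-base words in common with other genes, Cyp4a12a 48.9% and Sult2a1 33.2%, so the level of each member is uncertain. The count was 65 without wild-type vehicle library 2, 53 without wild-type vehicle library 3, and 62, 61, 49 and 148 without knockout vehicle libraries 1, 3, 4 and 5, respectively. DESeq2 on the recovered reads called 266 genes, the number in the authors' deposited table, of which 96 were among the 98.

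After PCB-153, Akr1b7 and Sult2a1 were also higher and genes of male liver lower in knockout livers. Akr1b7 stood at 34.2 ± 15.2 in wild type and 1052 ± 329 in knockout (log2 fold change 4.95 ± 0.38, adjusted p = 1.09e-07, n = 5 each) and Sult2a1 at 530 ± 634 and 13400 ± 3615 (5.39 ± 0.73, adjusted p = 0.000261). Hsd3b5 fell from 1333 ± 811 to 10.9 ± 12.3 (-7.09 ± 0.96, adjusted p = 0.000236) and Cyp4a12a, a fatty acid hydroxylase of male liver, from 826 ± 636 to 11.3 ± 8.97 (-5.96 ± 0.89, adjusted p = 0.000677). The uptake transporter Slco1a1 fell from 2531 ± 471 to 192 ± 178 (-4.07), and the major urinary protein gene Mup13 from 10830 ± 5846 to 878 ± 799 (-3.90). Cyp2b10, the classic target of the related receptor CAR, rose from 736 ± 299 to 2168 ± 408 (1.65 ± 0.25, adjusted p = 0.000756). Other large falls were Elovl3, which lengthens fatty acids (-3.96), Cyp4a12b (-5.21), and the pseudogenes Mup-ps17 (-3.99) and Serpina4-ps1 (-5.33). The metal-binding Mt2 (3.68) and Zbed4-ps1 (5.94) rose.

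Of the 23 male-biased genes, 20 fell in knockout livers after PCB-153, or 22 adjusted over the list alone, with a median log2 fold change of -2.07, among them Cyp2u1 (-2.33) and Selenbp2 (-1.71). Of the 24 female-biased genes, 10 rose and none fell, or 19 adjusted over the list alone (median 1.24), including the transcription factor Cux2 (3.76) and the steroid hydroxylase Cyp17a1 (2.66). Both lists passed camera with the preset correlation (adjusted p = 6.23e-42 and 5.22e-21) and with one estimated from the data (adjusted p = 0.0238 with an estimated correlation for each). Among 30 phase I enzymes 9 rose and 1 fell, or 17 and 2 adjusted over the list alone, with Cyp2c55 at 1.57, Cyp2c29 at 1.64 and Cyp2b10 higher and Cyp2d9 lower (-2.07). This list passed with the preset correlation (adjusted p = 7.74e-09; adjusted p = 0.303 with an estimated correlation). Among 31 conjugation enzymes 6 rose and Gstp1 fell, with the oestrogen sulfotransferase Sult1e1 (3.74), Papss2 (1.33) and Gstm3 (0.80) among those higher (adjusted p = 0.0117, and adjusted p = 0.487 with an estimated correlation). The bile acid exporters Abcb11 (0.55) and Abcc4 (1.61) rose. All 25 cholesterol synthesis genes had a higher mean and 37 of 44 interferon response genes a lower mean in knockout, and none of them passed singly. Both lists passed with the preset correlation (adjusted p = 6.71e-06 and 4.11e-06; adjusted p = 0.791 with an estimated correlation for each).

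Between PCB-153 livers limma called 234 genes, 96 higher and 138 lower in knockout, 149 of them by more than 2-fold. The count was 140 and 124 without wild-type PCB-153 libraries 1 and 2, respectively, and DESeq2 on the recovered reads called 394, as in the authors' deposited table. Mup13 has 92.8% of its 50-base words in common with other genes, so its own level is uncertain. Across genes, the genotype effects under the 2 exposures, which share no library, correlated at Pearson's r = 0.653 and Spearman's rho = 0.473. They shared 34 genes called higher and 31 called lower, where independent lists would share 0.321 and 0.376, and no gene was called in opposite directions. Genes are not independent replicates, so no p-value is given for these correlations.

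**Figure D2:**
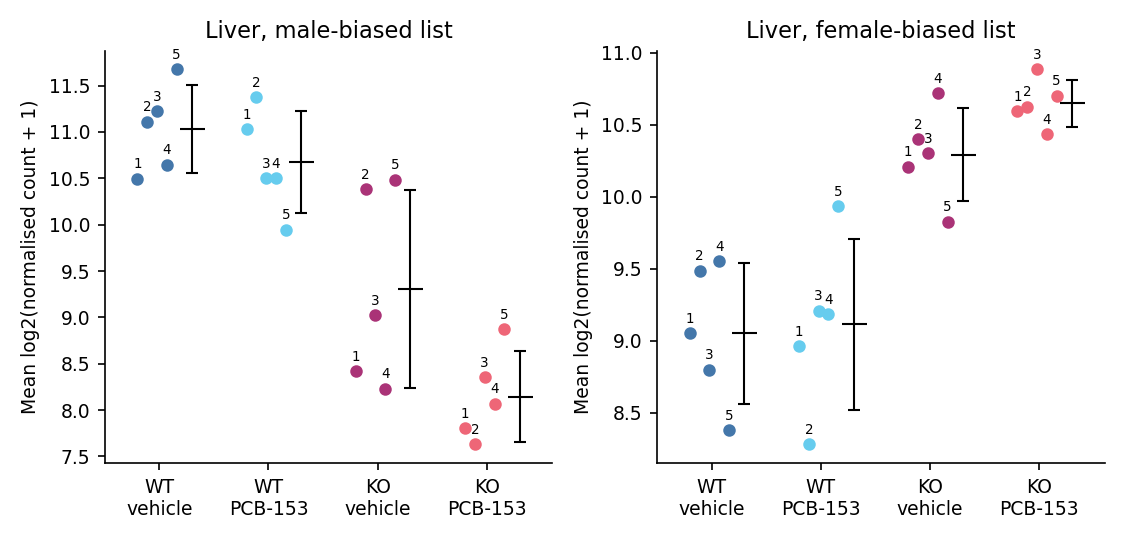
Mean log2(normalised count + 1) of the male-biased (left) and female-biased (right) gene lists in each liver library, by group, with numbered points for libraries and black bars for mean ± SD (n = 5). The male-biased mean is 11.03 and 10.67 in the wild-type groups and 9.31 and 8.15 in the knockout groups, and the female-biased mean is 9.05 and 9.11 against 10.29 and 10.65.

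The comparison of exposures within a genotype asks what perinatal PCB-153 changed at this age. In wild-type livers no single gene differed between PCB-153 and vehicle. The xenobiotic markers lay within the spread between replicates, with log2 fold changes of 0.29 ± 0.25 for Cyp2b10 (adjusted p = 0.754), -0.21 ± 0.17 for Cyp3a11 (adjusted p = 0.742) and -0.18 ± 0.30 for the dioxin-responsive Cyp1a1 (adjusted p = 0.879), n = 5 each. Cyp1a2 differed by -0.13 and Cyp2c55 by -0.11. By list, all 77 ribosomal protein genes and 40 of 43 nuclear-encoded respiratory chain genes had a higher mean after PCB-153, by medians of 0.20 and 0.18, and 26 of 30 genes of fatty acid oxidation a lower one, by a median of -0.23. All 13 mitochondrially encoded genes had a lower mean, also by a median of -0.23. These lists passed camera with the preset correlation (adjusted p = 1.25e-13, 1.75e-07, 0.000765 and 0.0099) and none of them with an estimated one (adjusted p = 0.842 with an estimated correlation for each). Limma called 0 genes, with 1081 at an unadjusted p under 0.05 where chance gives 808, and edgeR and DESeq2 on the recovered reads also called 0.

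In knockout livers no single gene passed the test either. Cyp2b10 was at 967 ± 216 under vehicle and 2168 ± 408 after PCB-153, with ranges that did not overlap (log2 fold change 1.17 ± 0.25, adjusted p = 0.115, n = 5 each). Cyp3a11 differed by 0.03 ± 0.17 (adjusted p = 0.963), and the direction of so small a value turned with the test used. In the neutrophil list 6 of 7 measured genes had a higher mean (median 0.66), 3 of them higher adjusted over the list alone. This list alone among those that passed in liver exposure comparisons did so under both correlations (adjusted p = 0.000206, and adjusted p = 0.0332 with an estimated correlation). Markers of other cells moved with it, with a higher mean in 21 of 23 macrophage genes (adjusted p = 0.000196), all 23 fibroblast genes (0.000167), 9 of 12 monocyte and dendritic genes (0.00276) and all 8 megakaryocyte genes (0.00883), with adjusted p = 0.626, 0.626, 0.623 and 0.59 with an estimated correlation. Knockout vehicle library 4 had the lowest neutrophil and macrophage means of these groups, 4.59 and 7.23. The neutrophil list mean was 4.96 ± 0.216 in knockout vehicle and 5.68 ± 0.225 in knockout PCB-153 livers (SD, n = 5 each). In wild type it was 5.44 ± 0.241 under vehicle and 5.64 ± 0.09 after PCB-153. The knockout PCB-153 mean thus lay near the wild-type means, and the knockout vehicle mean lay below them. As in wild type, ribosomal protein genes had a higher mean (76 of 77, adjusted p = 3.99e-14, and adjusted p = 0.626 with an estimated correlation) and all 13 mitochondrially encoded genes a lower one (adjusted p = 0.00713, and adjusted p = 0.81 with an estimated correlation). All 23 male-biased genes had a lower mean, 14 of them lower adjusted over the list alone (adjusted p = 3.23e-12, and adjusted p = 0.373 with an estimated correlation). In wild-type livers the mean of this list was also lower after PCB-153, at 10.67 ± 0.55 against 11.03 ± 0.47 (SD). The acute phase list had 5 genes higher adjusted over the list alone (adjusted p = 0.00111, and adjusted p = 0.327 with an estimated correlation), and the phase I list 2 (adjusted p = 0.000354, and adjusted p = 0.623 with an estimated correlation). The fatty acid synthesis list had 20 of 25 genes with a lower mean (adjusted p = 0.000206, and adjusted p = 0.373 with an estimated correlation).

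Limma called 0 genes between knockout livers, with 1592 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0959, while edgeR called 0 and DESeq2 61, as in the authors' deposited table. Without knockout PCB-153 library 4 limma called 3 genes, and without knockout vehicle library 2 it called 1. The difference of the exposure effects between genotypes was tested as an interaction, and again limma called 0 genes, with 435 at an unadjusted p under 0.05 and 0 by edgeR and DESeq2. The exposure effects in the 2 genotypes correlated across genes at Pearson's r = 0.407 and Spearman's rho = 0.449.

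In spleen, the genotypes under vehicle, as labelled, differed at few genes, most of them neighbours of Nr1i2 on chromosome 16. Pla1a, a phospholipase gene 0.15 Mb away (38396117 to 38433145), was at 9.29 ± 3.56 in wild type (n = 4) and 55.9 ± 17.2 in spleens labelled knockout (n = 5), a log2 fold change of 2.49 ± 0.27 (adjusted p = 5.66e-05). Ift57, needed for building cilia (49699233 to 49765126), rose from 145 ± 23.0 to 318 ± 39.6 (1.13 ± 0.11, adjusted p = 8.1e-06). The lymphocyte receptor gene Cd96 fell from 159 ± 24.1 to 83.6 ± 14.8 (-0.93, adjusted p = 0.0194) and the long noncoding RNA gene Dubr from 152 ± 26.4 to 67.7 ± 7.10 (-1.15, adjusted p = 0.000835). Rdh16f1, a retinol dehydrogenase gene on chromosome 10, was also called (0.91, adjusted p = 0.034), but 100% of its 50-base words occur in Rdh9 or other genes. Nr1i2 was the other call (5.38 ± 0.39, adjusted p = 9.42e-08). Cell type markers did not separate these groups singly. Cd79a of B cells differed by 0.00 ± 0.14 (adjusted p = 0.997), Cd3e of T cells by -0.05 ± 0.14 (adjusted p = 0.927) and the erythroid haem enzyme Alas2 by -0.13 ± 0.16 (adjusted p = 0.789).

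Among lists, 21 of 23 neutrophil and myeloid precursor genes had a lower mean in vehicle spleens labelled knockout (median -0.67), and 16 fell adjusted over the list alone against 0 over all genes tested (adjusted p = 2.54e-14, and adjusted p = 0.387 with an estimated correlation). All 40 proliferation genes had a lower mean (adjusted p = 3.79e-09, and adjusted p = 0.528 with an estimated correlation), and all 21 macrophage genes a higher one (adjusted p = 2.11e-07, and adjusted p = 0.497 with an estimated correlation). In the same comparison all 13 mitochondrially encoded genes had a higher mean (adjusted p = 6.03e-07), and all 43 respiratory chain genes (3.12e-10) and 66 of 77 ribosomal protein genes (1.42e-07) a lower one, with adjusted p = 0.497, 0.497 and 0.579 with an estimated correlation. Limma called 6 genes, 4 higher and 2 lower, edgeR called 10 and DESeq2 23. Without wild-type vehicle library 4 the count was 22, and with the genes of chromosome 16 left out, an alternative chosen after the data were examined, it was 0 (1933 at an unadjusted p under 0.05).

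After PCB-153, Ift57, Cd96, Dubr and Pla1a on chromosome 16 again differed between the genotypes in spleen, and further genes elsewhere. Ift57 rose from 149 ± 11.5 to 418 ± 28.4 (log2 fold change 1.48 ± 0.10, adjusted p = 1.84e-08, n = 5 each), Cd96 fell by 1.02, Dubr by 1.36 and Plcxd2 by 0.91 on the log2 scale, and Pla1a rose by 2.29. Igha, the constant region of immunoglobulin A, rose from 472 ± 126 to 2518 ± 1608 (2.18 ± 0.42, adjusted p = 0.0373). Also higher were Itgae, an integrin of resident T cells and dendritic cells (0.85), the cytokine signalling inhibitor Cish (0.77), Sema3g (0.86), the antioxidant enzyme Gpx3 (0.69), the antibody light chain segment Igkv1-110 (0.70) and the macrophage gene Cd5l (0.68). The B cell genes Fam129c (-0.67) and Klhl14 (-0.77), the interferon-inducible Slfn8 (-0.66) and Ifi214 (-0.65), and Adamts6 (-0.70) were lower in the spleens labelled knockout.

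The B cell list had 26 of 27 genes with a lower mean after PCB-153 in the spleens labelled knockout, 16 of them lower adjusted over the list alone and 0 over all genes tested (adjusted p = 2.69e-14, and adjusted p = 0.423 with an estimated correlation). Other lists moved with it: 28 of 29 T cell (adjusted p = 4.96e-07), 38 of 44 interferon (7.14e-09) and 19 of 20 megakaryocyte genes (7.04e-09) had a lower mean, and 19 of 21 macrophage (1.02e-07) and 20 of 25 fibroblast genes (8.45e-08) a higher one. For these, adjusted p = 0.528, 0.477, 0.423, 0.46 and 0.423 with an estimated correlation. All 33 erythroid genes had a higher mean, by a median of 0.30 (adjusted p = 2.38e-11, and adjusted p = 0.423 with an estimated correlation). All 26 pancreatic acinar genes had a higher mean in the same group, by a median of 3.92 (adjusted p = 8.28e-20, and adjusted p = 0.423 with an estimated correlation). Acinar genes took 1.79% of the reads of library 4 and 0.220% of library 1 of the PCB-153 spleens labelled knockout. In all, limma called 30 genes, 15 higher and 15 lower, against 33 by edgeR (22 higher and 11 lower) and 215 by DESeq2. The count was 11, 10, 12, 13 and 52 without wild-type PCB-153 libraries 1 to 5 in turn, and 17, 60, 19 and 119 without libraries 1, 2, 3 and 5 labelled knockout. It was 79 without libraries 1 and 4 labelled knockout together, 82 with the acinar and hepatocyte list means as covariates, 8 with chromosome 16 left out, and 14 in a fit of these 2 groups only. The genotype effects under the 2 exposures correlated across genes at r = 0.06 and rho = 0.031, and shared 5 called genes where independent lists would share 0.00315 higher and 0.00157 lower.

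Chromosome 16 near Nr1i2 held more genotype calls than the rest of the genome in both tissues. In liver Ift57 was higher in knockout under vehicle and PCB-153 (log2 fold change 2.02 and 1.98), as was Cd47, a surface protein that restrains phagocytes (0.67 and 0.76). Within 20 Mb of Nr1i2, itself not counted, 6 of 231 genes were called in vehicle livers (2.6% against 0.575% elsewhere, one-sided Fisher exact p = 0.00276) and 8 of 231 in PCB-153 livers (3.46% against 1.42%, exact p = 0.0197). In spleen these were 4 of 275 (exact p = 2.16e-07) and 7 of 275 (exact p = 1.51e-07). Of the 14 genes called there in any genotype comparison, 6 were higher and 8 lower in knockout, as labelled, and Ift57 was the 1 gene called in both tissues. Of the 10 measured in both tissues, 5 had the same sign in all 4 genotype comparisons, Ift57 and Cd47 among them, and 5 did not, among them Pla1a and Plcxd2. Neighbouring genes are not independent, and this test was chosen after the data were examined.

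**Figure D3:**
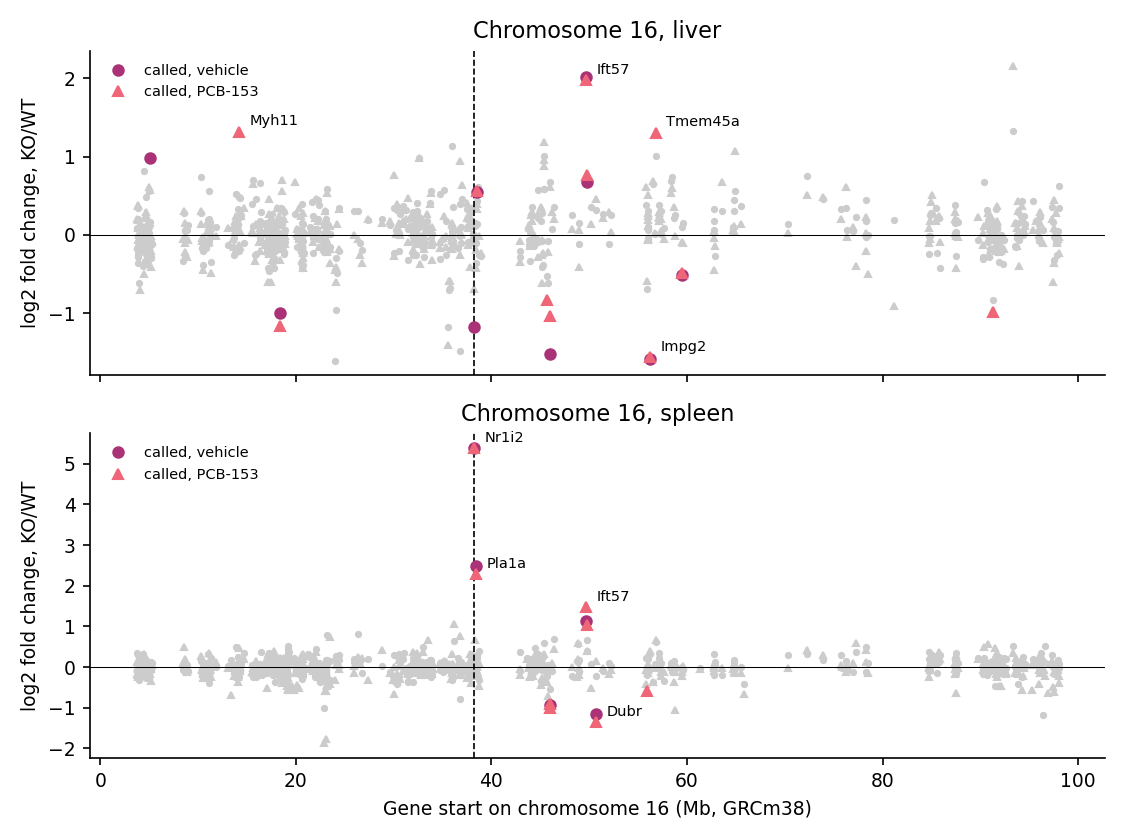
Log2 fold change between genotypes for genes tested on chromosome 16, by gene start (Mb, GRCm38), in liver (top) and spleen (bottom), with coloured circles (vehicle) and triangles (PCB-153) for genes called by limma, grey marks for the others and a dashed line at Nr1i2. In spleen all called genes of this chromosome lie within 20 Mb of Nr1i2, 4 under vehicle and 7 after PCB-153 besides Nr1i2 itself.

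In wild-type spleens no single gene separated PCB-153 from vehicle. Cd79a (-0.13 ± 0.14), Cd3e (-0.11 ± 0.14) and Alas2 (-0.08 ± 0.16) lay within the spread between replicates (n = 4 vehicle and 5 PCB-153 libraries). By list, 19 of 20 natural killer and cytotoxic genes and 22 of 23 neutrophil genes had a lower mean after PCB-153, with medians of -0.25 and -0.24, and all 40 proliferation genes a higher one (median 0.14). These lists passed camera with the preset correlation (adjusted p = 2.29e-07, 1.48e-06 and 0.000426) and not with an estimated one (adjusted p = 0.81, 0.835 and 0.879 with an estimated correlation). A lower mean was also seen in 25 of 27 B cell (adjusted p = 0.00142) and 23 of 29 T cell genes (0.00192), and a higher one in 29 of 33 erythroid (0.00417) and all 13 mitochondrially encoded genes (1.24e-06), with adjusted p = 0.879, 0.879, 0.879 and 0.835 with an estimated correlation. Without wild-type vehicle library 4 the erythroid list turned direction and did not pass (adjusted p = 0.904). Limma called 0 genes, with 727 at an unadjusted p under 0.05 where chance gives 953, edgeR called 0 and DESeq2 3.

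In the spleens labelled knockout, PCB-153 libraries had lower levels of B cell genes, lower means of most T cell genes, and higher levels of erythroid, cell division and neutrophil genes than vehicle libraries. Cd79a, part of the B cell receptor, fell from 6501 ± 758 to 4275 ± 1122 (log2 fold change -0.64 ± 0.13, adjusted p = 0.0212, n = 5 each) and Ms4a1, which encodes CD20, from 6321 ± 679 to 4227 ± 849 (-0.60, adjusted p = 0.0212). Klhl14 fell by 0.88 on the log2 scale (adjusted p = 0.00224) and Rag1, which cuts antigen receptor genes in lymphocyte precursors, by 1.16. Other large falls were Pde4c (-1.05), the antibody segment Ighv1-50 (-1.03) and Col5a3 (-0.98), and other large rises Apol10a (1.18), Apol11b (1.17) and Btn1a1 (0.96). Fech, the last enzyme of haem synthesis, rose from 13060 ± 2589 to 19000 ± 1340 (0.56 ± 0.12, adjusted p = 0.0251), and the erythroid transcription factor Nfe2 rose by 0.57. S100a8, a calcium-binding protein of neutrophils, rose from 736 ± 149 to 1151 ± 186 (0.65 ± 0.13, adjusted p = 0.0212). The acinar genes Try4 (5.76) and Ctrb1 (5.62) also passed, with Try4 at 9110 in library 4, 1150 in library 1, 37.3 in library 5 and at most 1.22 in the other PCB-153 libraries labelled knockout.

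Of 27 B cell genes 19 fell, or 24 adjusted over the list alone, including Bach2 (-0.75), Fcrla (-0.62) and Vpreb3 (-0.84). Of 33 erythroid genes 18 rose, or 27 adjusted over the list alone, including Epb42 (0.56) and Tspo2 (0.57). Of 40 proliferation genes 13 rose, or 39 adjusted over the list alone, with Cdc20 and Tpx2 both at 0.50, Cenpf at 0.51 and Racgap1 at 0.51. Of 23 neutrophil genes 9 rose, or 15 adjusted over the list alone, including S100a9 (0.66), Ltf (0.79) and Ngp (0.74). Camera passed these lists with the preset correlation (adjusted p = 5.27e-17, 1.23e-17, 1.75e-17 and 4.48e-10) and not with an estimated one (adjusted p = 0.314 with an estimated correlation, and 0.566 for proliferation). The NRF2 antioxidant list had 5 of 20 genes higher, among them Gclm (0.44), Slc7a11 (0.36), Txnrd1 (0.27) and G6pdx (0.22) (adjusted p = 0.000259, and adjusted p = 0.314 with an estimated correlation). Of 25 fibroblast genes 3 collagen genes rose, Col1a1 (0.44), Col5a1 (0.30) and Col6a2 (0.46) (adjusted p = 0.00506, and adjusted p = 0.674 with an estimated correlation). The interferon list had 2 of 44 genes lower, Mx1 (-0.86) and Ddx58 (-0.42) (adjusted p = 0.0172, and adjusted p = 0.781 with an estimated correlation). The monocyte and dendritic genes Siglech (-0.76) and Cd209a (-0.57), Il2ra, the interleukin 2 receptor chain of activated T cells (-0.65), Nrgn (-0.35) and Serpinc1 (-0.49) fell, while Chil3 (0.64) and the respiratory chain gene Uqcrc1 (0.25) rose. Of 29 T cell genes 27 had a lower mean (adjusted p = 2.83e-05, and adjusted p = 0.674 with an estimated correlation), as had 22 of 23 hepatocyte genes, Serpinc1 among them (median -1.21, adjusted p = 0.0142, and adjusted p = 0.781 with an estimated correlation). Vehicle library 4 held most hepatocyte reads, with a list mean of 8.89 against at most 3.72 in the other vehicle libraries, and the difference of list means was within the spread between libraries (exact p = 0.579). Without PCB-153 libraries 1 and 4 the T cell mean differed by -0.03 (exact p = 0.768) and the proliferation mean by 0.27 (exact p = 0.232), against -0.23 and 0.46 with all libraries. Of 26 acinar genes 5 rose, or 26 adjusted over the list alone, including Amy2b (5.08) and Cpb1 (4.88) (adjusted p = 3.54e-12, and adjusted p = 0.569 with an estimated correlation). The PCB-153 libraries labelled knockout with the most acinar reads also had the lowest B cell means, 10.52 in library 1 and 10.58 in library 4 against 10.80 to 11.26 in libraries 2, 3 and 5.

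Limma called 1010 genes in this comparison, 530 higher and 480 lower, 31 of them by more than 2-fold. EdgeR called 960 and DESeq2 2027, the number in the authors' deposited table, and after quantile normalisation limma called 362 higher and 498 lower. The count rested on single libraries: it was 403, 42, 118 and 20 without vehicle libraries 2, 3, 4 and 5, and 42, 3704, 16, 10 and 2224 without PCB-153 libraries 1 to 5 in turn. It was 23 without PCB-153 libraries 1 and 4, 15 without 1, 4 and 5, 0 with the acinar and hepatocyte list means as covariates (1999 at an unadjusted p under 0.05), 184 in a fit of these 2 groups only and 232 with no filter on low values. The interaction test of the exposure effects between genotypes called 0 genes by limma (1877 at an unadjusted p under 0.05, smallest adjusted p = 0.417) and by edgeR, and 31 by DESeq2. Without PCB-153 library 1 labelled knockout, limma called 2 genes in the interaction. Across genes the exposure effects in the 2 genotypes correlated at r = 0.083 and rho = 0.225.

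**Figure D4:**
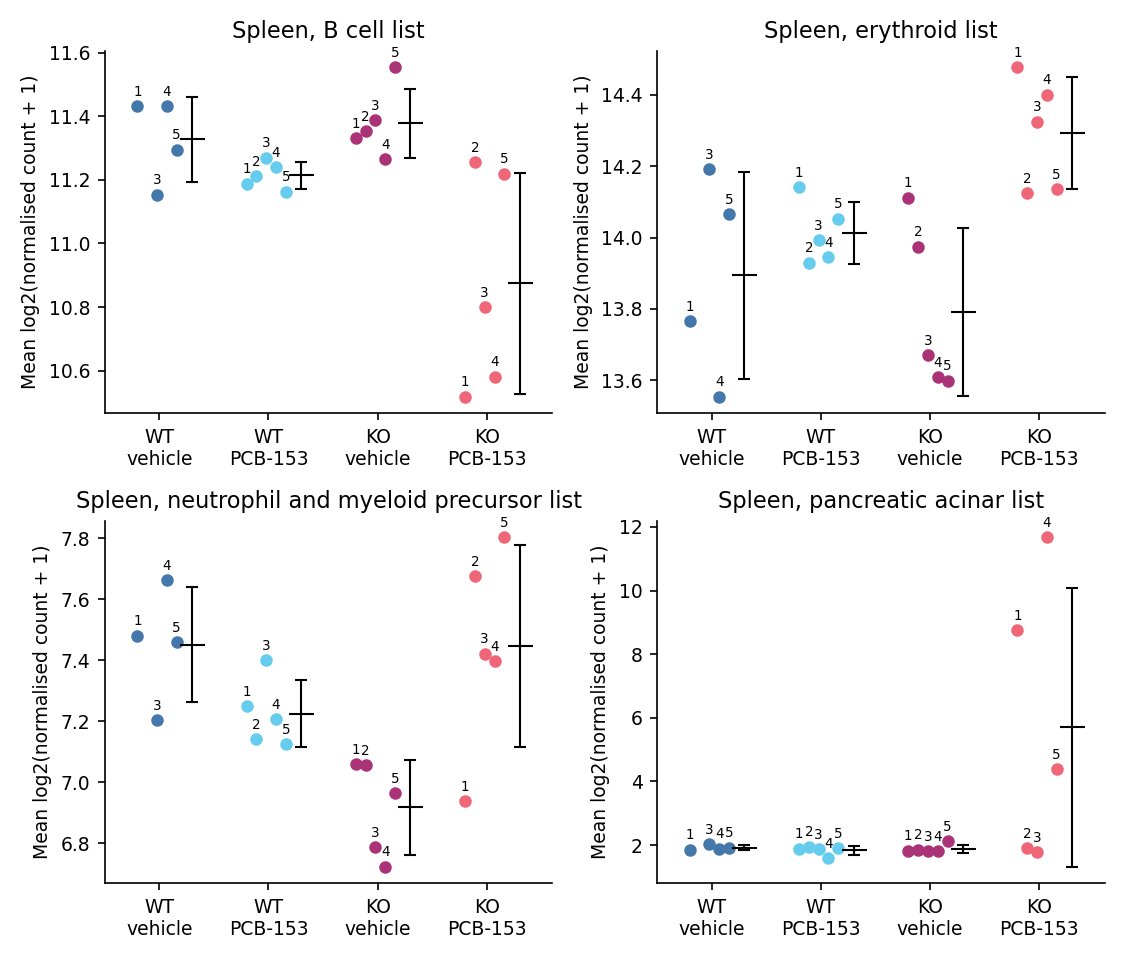
Mean log2(normalised count + 1) of 4 gene lists in each spleen library, by group, with numbered points for libraries and black bars for mean ± SD (n = 4 for wild-type vehicle, 5 for the others). In the PCB-153 group labelled knockout, B cell means run from 10.52 to 11.26, and acinar means reach 11.68 in library 4 and 8.75 in library 1.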

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

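The tests of patterns below were all chosen after the results were seen, except the counts of regrouped libraries, which were planned before. Spleen directions between genotypes rest on the label of knockout. Of 478 groups of values, 31 held 1 library far from the others, and chance flags about 1 in 20 groups, or 24 here.

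In liver, PCB-153 knockout library 5 had 28647032 reads, where the other libraries of its group had 18253070 to 19845149. Single libraries also stood apart for Cyp2d41-ps (1150 in wild-type vehicle library 1, others at most 292), Prom1 (514 in knockout vehicle library 4, others at most 259) and Pnpla3 (149 in knockout vehicle library 5, others at most 61.3). Among list means, interferon response was high in wild-type vehicle library 3 (8.47), macrophage and neutrophil low in knockout vehicle library 4 (7.23 and 4.59), neutrophil low in wild-type PCB-153 library 1 (5.48) and haematopoietic progenitor high in wild-type PCB-153 library 5 (5.42).

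In spleen, single libraries far from their group were found for the lymphocyte genes Cd3e (732) and Bach2 (1800) in labelled knockout vehicle library 5, Cd79a in the same library (7830), in wild-type vehicle library 3 (5960) and in wild-type PCB-153 library 3 (6470), and Cd96 in wild-type PCB-153 library 3 (114). All reads of Nr1i2 in wild-type spleens came from vehicle library 4 (2.27) and PCB-153 library 1 (2.23). Labelled knockout vehicle library 1 was low for Txnrd1 (1180) and high for Cdc20 (1440) and Racgap1 (2180), and library 2 of that group was high for Ighv1-50 (463) and low for Cpb1 (0.914). In labelled knockout PCB-153 spleens Plcxd2 was low in library 3 (38) and Igkv1-110 high in library 2 (2220), and Sema3g was low in wild-type PCB-153 library 2 (216). Among list means, the flagged libraries were wild-type PCB-153 library 5 for interferon response (9.83) and library 4 for acinar genes (1.58), and, of those labelled knockout, vehicle library 3 for mitochondrially encoded genes (14.31), library 4 for hepatocyte genes (8.89), library 5 for acinar genes (2.11) and PCB-153 library 5 for NRF2 genes (10.07).

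Other results stand out because, of the lists tested for an interaction of PCB-153 and genotype, 24 passed with the preset correlation, although no single gene did. None held with an estimated correlation, the smallest being adjusted p = 0.194 with an estimated correlation in liver and 0.209 in spleen. In liver the camera adjusted p with the preset correlation was 1.71e-07 for phase I enzymes, 1.97e-05 for fatty acid oxidation, 1.22e-05 for both male-biased and pericentral hepatocyte genes, 8.76e-05 for acute phase, 0.000991 for interferon response, 0.00555 for proliferation, 0.0156 for neutrophil, 0.0174 for macrophage, 0.0305 for female-biased genes and 0.0414 for fatty acid synthesis. In spleen it was 1.4e-17 for neutrophil, 3.35e-11 for erythroid, 1.38e-11 for acinar, 3.54e-10 for B cell and 2.48e-09 for proliferation genes. Further spleen lists were respiratory chain (5.87e-06), ribosomal protein (6.17e-05), mitochondrially encoded (0.000209), NRF2 (0.000426), cholesterol synthesis (0.00143), fibroblast (0.00473), hepatocyte (0.0415) and stress response (0.0449).

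Whether groups separate by more than any regrouping of libraries was tested on 100 splits of the same libraries, the real one included. The real grouping alone reached its count in liver between genotypes, 1 of 100 under vehicle (98 genes; highest other 1) and 1 of 100 after PCB-153 (234; highest other 42). In spleen 4 of 100 splits reached the 1010 genes between exposures in labelled knockout (highest other 1832), 3 of 100 the 6 genes between genotypes under vehicle (highest other 130) and 3 of 100 the 30 genes after PCB-153 (highest other 2346). Where 0 genes were called, all 100 of 100 splits reach that count by construction, so nothing follows about the groups; the highest others were 2027 for exposure in wild-type liver, 45 in knockout liver, 10 for the liver interaction, 14 for exposure in wild-type spleen and 2044 for the spleen interaction. Splits that call more genes than the real groups show that libraries also differ by something other than group.

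Spleen B cell genes were lower and erythroid genes higher in labelled knockout after PCB-153, the group with pancreatic reads. Dilution by pancreatic RNA does not explain it, because acinar genes took at most 1.79% of reads while the median B cell member fell by 31.4%. An effect of libraries 1 and 4 alone and a change of the whole group cannot be told apart. Without them the B cell mean differed by -0.29 (exact p = 0.0179, the smallest possible, and 0.0955 adjusted, against 0.0635 adjusted with all libraries). The SD of the vehicle group was 0.108. Both B cell exact p-values, 0.0179 here and 0.00794 with all libraries, were the smallest their numbers of splits allow. Each could pass after adjustment only if more lists shared that smallest value, so the adjusted values cannot decide this question. Without libraries 1 and 4 the erythroid mean differed by 0.40 (exact p = 0.0357, and 0.143 adjusted). For erythroid genes libraries 2, 3 and 5 stood at 14.125, 14.324 and 14.136, and the highest vehicle library at 14.112. Libraries 2 and 5 thus exceeded it by much less than the vehicle SD of 0.235. For B cell genes library 3 stood at 10.80 and libraries 2 and 5 (11.26 and 11.22) near the lowest vehicle library (11.27), and without libraries 1 and 4 Cd79a went from -0.64 to -0.38 and was no longer called. A larger erythroid share that lowers all other cells alike predicts a lower neutrophil mean. That mean was higher by 0.53 (pooled SD 0.259, exact p = 0.0317, and 0.127 adjusted). This goes against such a share as the only cause, but the adjusted p did not pass. A separate neutrophil change on top of it and a biological change in the cells were not tested.

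Genotype calls lay close to Nr1i2 on chromosome 16 in both tissues. DNA of a donor strain kept around the targeted gene and an effect of the receptor on its neighbours both predict more calls within 20 Mb than elsewhere. This was seen in both tissues (largest one-sided Fisher exact p of the 4 genotype comparisons 0.0197), so in liver these causes cannot be told apart. In spleen the wild-type vehicle and PCB-153 groups held only 3 and 2 Nr1i2 reads in all. As labelled, that argues against loss of the receptor in spleen itself as the cause of the calls there. A variant haplotype whose reads align less often predicts lower values, yet 6 of the 14 called genes were higher in knockout, which excludes it as the only cause.

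Male-biased genes were lower and female-biased genes higher in knockout livers. Female or mixed groups are excluded, as Eif2s3y was at least 607 (606.9) in every knockout liver. Sharing of reads within gene families is excluded only as the sole cause. Of the called members, 7 under vehicle and 14 after PCB-153 have under 10% of their words in common with other genes, 3 and 9 of them male-biased. A first measure by symbol had left 2 called members outside families under each exposure, fewer than the rule asked for, and was replaced. Across 20 livers, deviations from the group means of 14 perinatal genes and of the male-biased list correlated at r = -0.964 (permutation p = 1e-05, the smallest possible; female-biased r = 0.443, permutation p = 0.0264, Spearman's rho = 0.37, permutation p = 0.111), which shows that they vary together and not that knockout livers are less mature. The perinatal mean was higher in knockout after PCB-153 by 1.06 (exact p = 0.00794, the smallest possible). Lower maturity fits there as part of the cause, though of the 14 genes only Peg3 passed (limma adjusted p = 0.00503). H19 (log2 fold change 3.71) and Igf2 (2.08) moved most, without passing. Afp (0.403), Cd24a (0.384), Igf2bp3 (0.258) and Mest (0.235) moved little, Meg3 was lower (-0.433), and the remaining genes lay between Afp and Igf2. With the perinatal mean as covariate the male-biased list still differed (adjusted p = 0.000427 with an estimated correlation, median from -2.07 to -0.94, genes called lower from 20 to 10). This does not decide whether lower maturity is the whole cause, since a mean of 14 genes measures it imperfectly and may leave a difference. The female-biased median moved little (1.24 to 1.12, genes called higher from 10 to 5, adjusted p = 0.0238 before and 0.0819 after, with an estimated correlation). Under vehicle the perinatal mean differed by 0.86 (exact p = 0.127), none of its genes passed, and the list with the covariate had adjusted p = 0.0642 with an estimated correlation (median from -1.33 to -0.64, genes called lower from 10 to 2; female-biased 0.98 to 0.87, genes called higher from 6 to 2, adjusted p = 0.223 with an estimated correlation), so there maturation, as part or whole of the cause, and an effect of the receptor cannot be told apart.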

How the results depend on the processing

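Counts of called genes depended on the test and on single libraries, and no cause was tested unless stated. Depth limits which genes reach the minimum mean of 10; the spread between replicates exceeds counting error, with a chi-square per degree of freedom of at least 9.98 in liver and 4.67 in spleen. The settings named as added were chosen after the data were examined.

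DESeq2 called 61 (exposure in knockout), 266 and 394 genes (genotype under vehicle and PCB-153) in liver, and 3, 2027, 23, 215 and 31 in spleen (exposure in wild type and labelled knockout, genotype under vehicle and PCB-153, interaction). The authors' deposited spleen tables hold slightly more for exposure in wild type (4) and for genotype under vehicle (24) and PCB-153 (219). EdgeR called 10 in spleen between genotypes under vehicle. With no filter, 1 gene was called between knockout livers by exposure and 232 in spleen; with a mean of at least 50, 64 in liver and 3 in spleen between vehicle genotypes. A fit of only the compared groups gave 184 for exposure in labelled knockout and 14 for genotype after PCB-153 in spleen. With the replicate number as a block the latter was 18 and Cd79a between vehicle spleens was -0.021 (0.00 without). By deviations from group means, only 3 of 20 livers and 5 of 19 spleens correlate best with a library of their own number. Pairs of the same number had a median correlation of 0.031 in liver and 0.064 in spleen, against -0.009 and -0.006 for other pairs. Weak matching by number is therefore not excluded. Cyp3a11 in liver turned from -0.21 to 0.0103 in wild type after quantile normalisation, and from 0.03 to -0.00573 with edgeR and -0.000222 with DESeq2 in knockout.

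Added settings: with the perinatal mean as covariate, liver genotype calls were 51 under vehicle and 83 after PCB-153. Cyp1a1 turned to 0.107 (from -0.50) under vehicle and 0.361 (from -0.38) after PCB-153, where Cyp1a2 turned to 0.0868 (from -0.44) and Cyp3a11 to 0.264 (from -0.15). Proliferation (adjusted p = 0.814) and pericentral (0.772) lists turned under vehicle and fibroblasts (0.0793) after PCB-153. In spleen, leaving out chromosome 16 gave 0 and 8 genotype calls under vehicle and PCB-153; besides the genes left out, calls elsewhere fell from 1 and 22. Without labelled knockout PCB-153 libraries 1 and 4, exposure calls were 23 and genotype calls 79; without 1, 4 and 5 exposure calls were 15; with the acinar and hepatocyte means as covariates they were 0 and 82. In these settings Nr1i2 by exposure turned to 0.0104, 0.0048 and 0.206 (from -0.09), Cd3e by genotype to 0.0381, 0.0588 and 0.0823 (from -0.21), and Cd3e by exposure with covariates to 0.015 (from -0.28).

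With 1 library left out at a time, calls ranged from 49 to 148 (liver genotype, vehicle), 124 to 337 (PCB-153), 0 to 3 (liver exposure, knockout), and in spleen from 4 to 22 and 10 to 119 (genotype, vehicle and PCB-153), 10 to 3704 (exposure, labelled knockout) and 0 to 2 (interaction). Log2 fold changes by exposure in knockout liver ranged from -0.292 to 0.155 for Cyp1a1, -0.0605 to 0.279 for Cyp1a2 and -0.118 to 0.152 for Cyp3a11. In spleen they ranged from -0.427 to 0.338 for Nr1i2 by exposure in wild type, and between vehicle genotypes from -0.127 to 0.0159 for Cd3e and -0.0663 to 0.0314 for Cd79a. Adjusted p ranged from 6.21e-07 to 0.699 for ribosomal proteins between vehicle livers, and by exposure in wild-type spleen from 2.39e-06 to 0.904 for erythroid genes and 4.73e-17 to 0.899 for ribosomal proteins, the direction turning at the highest p of each.

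Over all settings, 2534 results for named genes kept direction and call, 755 lost the call, 11 gained it and 28 turned. For lists 1462 kept, 347 lost and 6 turned, but 1296 of those kept came from leaving out single libraries at the preset correlation. With an estimated correlation only 3 list results kept the call and 127 lost it. The sex-marker covariate was not run because all libraries carry the male pattern.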

Other observations

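The pigment cell genes Dct and Tyrp1 were high in the same 6 spleens. Dct, an enzyme of melanin synthesis, was at 335, 519 and 226 in wild-type vehicle libraries 1, 4 and 5, at 240 in vehicle library 5 labelled knockout and at 141 and 584 in PCB-153 libraries 2 and 3 labelled knockout, and at most 4.18 elsewhere. Tyrp1, another melanin enzyme, followed the same libraries at 126, 209, 88.8, 95.2, 57.2 and 273 and was 0 elsewhere. Pmel, a pigment granule protein, was present in every spleen, at 223 to 466 in these libraries and at 99.7 to 174 in the others. Dct was lower after PCB-153 in wild-type spleens by a log2 fold change of -6.19 ± 1.67 and did not pass (limma adjusted p = 0.943).

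Albumin, made by hepatocytes, was at 8920 in vehicle library 4 labelled knockout, 2850 in wild-type PCB-153 library 1 and 1010 in wild-type vehicle library 1 of spleen. In knockout livers the genes nearest to a call for PCB-153 against vehicle all had a limma adjusted p of 0.0959, among them the lipid enzymes Scd1 (log2 fold change -1.62) and Elovl5 (-0.78), the iron-binding Lcn2 (1.62), the macrophage receptor Marco (1.70) and Gpc3 (1.75), a surface protein of fetal liver.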
